A study of Mus musculus with 6 samples.

How the data were processed

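RNA from cardiomyocyte-enriched cell populations of C57BL/6J mice was measured on 6 one-colour Illumina MouseWG-6 v2 BeadChip arrays, 2 in each of 3 groups: sham surgery with no drug named (sham), transverse aortic constriction with DMSO vehicle (TAC_DMSO), and transverse aortic constriction with the drug BIX-01294 (TAC_BIX). Per the labels, BIX-01294 was given for 1 week from subcutaneous osmotic pumps; how long vehicle was given is not stated. The RNA was purified with Trizol and RNeasy columns and treated with DNase I, its quality was checked on a Bioanalyser, and it was amplified to biotin-labelled cRNA with the Ambion TotalPrep kit. Per the submitters' processing notes, GenomeStudio 2011.1, lumi and limma were used. What each did, and how background and differences between arrays were handled, are not given in the sources used here. Each array is described as a biological replicate; the number of mice behind one array, the slide positions and the time of day at collection are not given in the sources used here.

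The deposited signal table held, for each array and probe, an average bead signal intensity as exported by the authors, with no normalization between arrays and no background subtracted: the lowest signal was 87.5, and the column means differed. Beside each signal the authors deposited a detection p-value, in steps that correspond to 936 negative controls. The authors' processed table held log2 values that shared one distribution on all 6 arrays, with a median of 7.19 on each, and ranked the probes as the signal table did on all 6 arrays. Between 36.7% and 40.9% of the 45281 probes were detected per array, and the number of arrays limits the precision of every value.

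The signal table was the starting point. Signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16 added before the log2 transformation. Of the 45281 probes, 34885 belonged to 1 gene in the platform's annotation, 18 to several and 10378 to none. Entrez identifiers matched 34807 probes to the reference gene table (GRCm38.p6), which changed 0 symbols. Probes with a detection p-value under 0.05 on at least 2 of the 6 arrays were kept, which left 19273 probes, 16446 of them with 1 gene. A gene was represented by its kept probe with the highest mean over all arrays; 4005 of the 10538 genes tested had several kept probes, and disagreement of sign between them is stated beside the genes named. Probes with no gene or several were left out of the gene tests. Where a gene was below detection on both arrays of the lower group, the change is given as "at least" a fold. That bound set the higher group's mean against the mean, over the lower group's arrays, of the gene's own signal or the lowest normalized signal of a detected probe on that array, whichever was higher; those lowest signals were 4.80 to 4.99 on the log2 scale. Genes named that were detected on 1 of the 2 arrays of the lower group are said to be so, and their differences can be compressed by that floor.

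A model with 1 mean per group was fitted to all 6 arrays with limma (lmFit and eBayes, no intensity trend, not robust), with 3 residual and 4.62 prior degrees of freedom and a prior SD of 0.206 on the log2 scale. The 3 comparisons were TAC_DMSO with sham, TAC_BIX with TAC_DMSO, and TAC_BIX with sham; differences are the first group minus the second, with the model's standard error (SE) beside them and the SD of the 2 arrays beside group means. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 10538 genes, and genes with an adjusted p under 0.05 were called. The p-values measure the spread among these 6 arrays. Of 29 gene lists, 26 had at least 5 measured members and were tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 26 lists; the adipocyte, germline and sex-linked lists had 2, 4 and 3 measured members and were not tested. The lists, the tests, the thresholds and the named-gene rule were set before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap (provisional symbols left out), the 5 with the smallest p where fewer than 5 were called, up to 4 members with the smallest p in each list described, and a panel of 11 genes (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ehmt1, Ehmt2, Col1a1, Col3a1 and Ccn2); genes named outside it are said to be so.

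The procedure was tested on simulated arrays with the real genes' means and the model's moderated spread. In them 100 of 10538 genes differed by 1 log2 unit and 100 by 2. In TAC_DMSO against sham 67% of the smaller and 100% of the larger changes were recovered, and 13 unchanged genes were called. In TAC_BIX against TAC_DMSO these values were 72%, 100% and 12, and in TAC_BIX against sham 69%, 99% and 12. The moderated spread is drawn towards a common value, so fewer changes of these sizes may be recovered from real arrays. Myl4, at -2.93 log2 in TAC_BIX against TAC_DMSO, was not called there. A gene that was not called is therefore not shown to be unchanged. A list shifted by 0.5 log2 units was called in each of the 3 comparisons, and 0 others were. With an estimated correlation that list had camera adjusted p = 0.118, 0.0562 and 0.0480 in the same order, although its genes were truly shifted and independent. The estimated correlation therefore has little power with 2 arrays per group. A high adjusted p under it does not show that a list is unshifted or that correlation produced its call. The simulated genes varied independently of each other. In the real arrays the estimated correlation within a list reached 0.802, for extracellular matrix and fibrosis. The simulation therefore does not show how often a list of correlated genes is called without a shift.

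The alternatives tried were log2 quantile normalization without background correction, median scaling in place of quantile normalization, an offset of 50, the authors' processed values, no detection filter, detection on all 6 arrays, the mean of a gene's kept probes, every kept probe on its own, the 4 arrays of each comparison alone, an intensity trend with a robust prior, array weights, a fold of at least 1.5, an adjusted p under 0.01, a term for the replicate number, and leaving out each array in turn. For the lists, ranks in place of moderated statistics and an estimated inter-gene correlation were tried as well. For the relations between comparisons, different control arrays were tried in each difference. A removal of the trend with gene span was chosen after seeing the data. Gene spans came from the reference table and were available for 99.9% of the genes tested. With 2 arrays per group, few other splits of the samples exist, too few for a test, and genes called in them were not counted. With median scaling the median difference of all genes was -0.136 in TAC_BIX against sham, -0.0854 in TAC_DMSO against sham and -0.0359 in TAC_BIX against TAC_DMSO. With quantile normalization these medians were -0.00363, -0.0139 and 0.0334, so directions of lists were compared across scalings relative to that median. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.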

Results

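Gene expression was measured on 6 arrays of cardiomyocyte-enriched populations from mouse hearts. Transverse aortic constriction narrows the aorta and makes the left ventricle pump against a higher pressure, which leads to cardiac hypertrophy. BIX-01294 is an inhibitor of G9a and GLP, the histone H3 lysine 9 methyltransferases encoded by Ehmt2 and Ehmt1. There were 2 arrays each for sham surgery, constriction with vehicle (TAC_DMSO) and constriction with drug (TAC_BIX). The sham arrays detected 16634 and 16827 of 45281 probes, the TAC_DMSO arrays 18210 and 17101, and the TAC_BIX arrays 18072 and 18501. Mean signal intensities were 358 and 296 for sham, 433 and 391 for TAC_DMSO, and 425 and 439 for TAC_BIX. Replicate arrays correlated across probes with r = 0.986 in sham, 0.982 in TAC_DMSO and 0.988 in TAC_BIX, and arrays of different groups with r = 0.959 to 0.983. Hemoglobin and other erythroid transcripts differed between replicates of a group: Hba-a1, an alpha globin gene, measured 12.72 and 9.55 on the log2 scale in sham, 13.60 and 14.76 in TAC_DMSO, and 12.86 and 10.71 in TAC_BIX. Fibrosis-related transcripts also differed between replicates. The median deviation of the extracellular matrix list from each gene's mean was 0.84 and -0.26 log2 in the TAC_DMSO arrays, 0.06 and 1.00 in the TAC_BIX arrays, and -0.94 and -0.83 in sham.

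**Figure D1:**
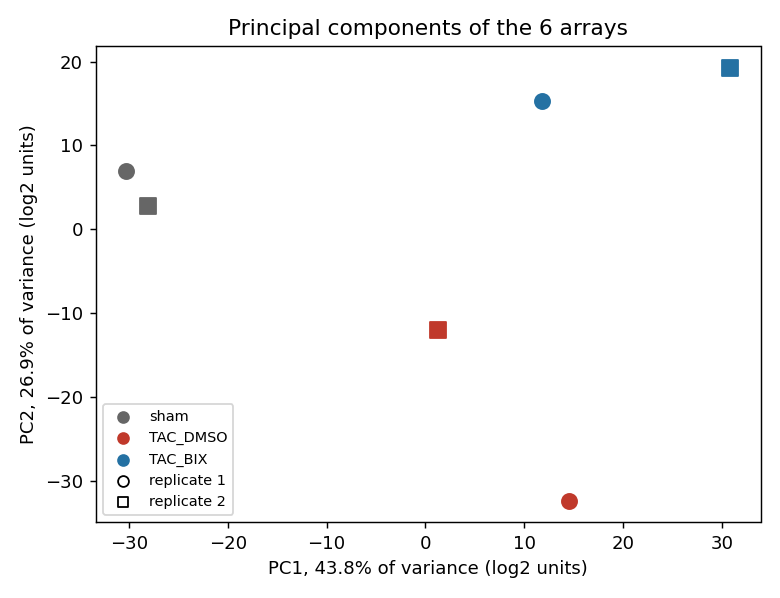
Principal components of the normalized log2 signals of the 6 arrays, with the first component (43.8% of variance) on the x axis and the second (26.9%) on the y axis; each point is an array, coloured by group and shaped by replicate. The sham arrays lie at -30.3 and -28.1 on the first axis and all 4 constriction arrays above 0, and the second axis separates TAC_BIX (15.3 and 19.3) from TAC_DMSO (-32.3 and -12.0).

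The comparison of TAC_DMSO with sham asks how the transcripts of these cells differed after constriction with vehicle. No vehicle is named for sham, so an effect of constriction cannot be told apart from one of the vehicle. Acta1, the skeletal alpha-actin gene of the fetal heart programme, was 3.95-fold higher in TAC_DMSO. It measured 14.71 ± 0.01, against 12.72 ± 0.11 in sham (log2 signal, SD, n = 2 per group, limma adjusted p = 0.0268). Nppa, which encodes atrial natriuretic peptide, rose 2.47-fold, from 13.44 ± 0.23 to 14.74 ± 0.09 (adjusted p = 0.0499). Both genes lay near the highest signal measured (14.98) in TAC_DMSO, where a fold can be compressed. The largest rise was that of Col8a1, a short-chain collagen gene, at 3.05 ± 0.39 log2 (SE; adjusted p = 0.0485). Clock genes moved in opposite directions: Ciart, a repressor of the clock, rose by 2.00 ± 0.18 and the clock output gene Dbp by 1.64 ± 0.18, while Arntl, which encodes the core activator BMAL1, fell by 2.12 ± 0.30 (adjusted p = 0.0268, 0.0439 and 0.0499). Retnla, a gene of alternatively activated macrophages, fell by 2.84 ± 0.35, to detection on 1 of the 2 TAC_DMSO arrays, and Kcnv2, a modifier subunit of potassium channels, fell by 1.78 ± 0.24 (adjusted p = 0.0439 and 0.0499).

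In all, 43 genes were called, 22 higher and 21 lower in TAC_DMSO, with log2 differences of at least 1.12 in size. Among the other large rises were Mybpc2, the fast skeletal myosin-binding protein C gene (4.42-fold), the interferon-induced antiviral gene Rsad2 (3.89-fold), the dynactin gene Dctn1 (3.49-fold), Gask1b (3.38-fold) and the homeobox gene Rhox5 (3.21-fold). Cav2, a caveolin gene, was not detected in sham (4.52 ± 0.19 against 6.14 ± 0.25) and was at least 2.23-fold higher. The other large falls were those of the dihydrodiol dehydrogenase gene Dhdh (3.10-fold), the integrin gene Itgb6 (2.91-fold), Mpst, a sulfurtransferase gene (2.85-fold), and the transcription factor gene Zhx2 (2.83-fold). Adam20 (from 7.23 ± 0.61 to 4.85 ± 0.40) and the adhesion receptor gene Celsr2 (from 6.45 ± 0.02 to 4.96 ± 0.20) also fell, each to the detection floor and detected on 1 of the 2 TAC_DMSO arrays. Zfp827 was not detected in TAC_DMSO (4.72 ± 0.10 against 6.19 ± 0.15) and was at least 2.49-fold lower.

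Several other members of the marker panel for hypertrophy and fibrosis did not pass. Col1a1 and Col3a1, the main fibrillar collagen genes, differed by 2.83 ± 0.78 and 1.90 ± 0.53 log2 (adjusted p = 0.107 and 0.110), with SDs of 1.51 and 1.24 between the TAC_DMSO arrays. Nppb, the gene of B-type natriuretic peptide, differed by 0.62 ± 0.20, Myh7, the fetal myosin heavy chain gene, by 1.39 ± 0.93, and the growth factor gene Ccn2 by 0.49 ± 0.37 (adjusted p = 0.141, 0.415 and 0.465). The adult myosin gene Myh6 differed by -0.09 ± 0.17 and Atp2a2, the sarcoplasmic calcium pump gene, by 0.08 ± 0.17, the latter with probes that disagreed in sign; both lay near the highest signal measured. Ehmt1 was not detected in sham and lay at the detection floor in TAC_DMSO (4.85 ± 0.02 and 4.98 ± 0.06), at least 1.00-fold higher without passing (adjusted p = 0.665). Ehmt2 differed by 0.03 ± 0.17 with probes that disagreed.

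By list, the interferon response had the smallest p: all 20 measured genes were above sham, with a median of 0.88 log2, 1 rose over all genes (Rsad2) and 15 rose adjusted over the list alone (camera adjusted p = 4.14e-11, and adjusted p = 0.721 with an estimated correlation). Further examples were the chemokine gene Cxcl9 (1.72), Ifit2 (1.60) and Usp18 (1.55), which did not pass over all genes (adjusted p = 0.0539, 0.0544 and 0.0544). All 27 measured extracellular matrix and fibrosis genes were above sham, with a median of 1.12; Col8a1 rose over all genes and 14 rose adjusted over the list alone (adjusted p = 1.99e-10, and 0.721 with an estimated correlation). Sparc, a matrix glycoprotein gene, differed by 2.22, the basement membrane collagen gene Col4a2 by 0.87 and Tgfb2 by 1.28. Fibroblast markers moved with this list between the arrays: their median deviation was 0.43 and -0.32 in TAC_DMSO and -0.42 and -0.37 in sham, with a median difference of 0.46 (adjusted p = 0.0569). Of 22 hypertrophy and fetal genes, 2 rose (Acta1 and Nppa) and 6 rose adjusted over the list alone, with 18 above 0 and a median of 0.53 (adjusted p = 1.15e-05, and 0.721 with an estimated correlation). The stretch-responsive gene Ankrd2, not detected in sham, was at least 1.78-fold higher (adjusted p = 0.0564).

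The cell cycle and endothelial lists were also called as higher. Of 25 cell cycle genes, 23 were above 0 with a median of 0.65, 0 passed over all genes and 0 adjusted over the list alone, against 43 called of all 10538 genes (camera adjusted p = 0.000337, and 0.721 with an estimated correlation). Cyclin D1 (Ccnd1) differed by 0.76, Aurka by 0.94 and the thymidylate synthase gene Tyms by 1.33, the last 2 detected on 1 of the 2 sham arrays. The median deviation of this list was -0.83 and 0.20 in the sham arrays and 0.76 and -0.10 in TAC_DMSO, so sham replicate 2 lay above TAC_DMSO replicate 2. Macrophage and leukocyte markers moved with it array by array, at -0.47 and 0.42 in sham and 0.70 and -0.22 in TAC_DMSO. Of 19 endothelial genes, 15 were above 0 with a median of 0.50, 0 rose over all genes and 5 rose adjusted over the list alone (adjusted p = 0.000913, and 0.721 with an estimated correlation). Gpihbp1, the capillary anchor of lipoprotein lipase, differed by 1.87, Ramp2 by 1.21 and Ly6c1 by 1.12.

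Of the lists of cardiomyocyte function, 3 were called as lower, while the sarcomere (median -0.05, adjusted p = 0.858) and cardiac transcription factors (median -0.14, adjusted p = 0.358) were not called. The 3 lists were lowest in TAC_DMSO replicate 1, where the matrix (0.84), leukocyte (0.70) and fibroblast (0.43) lists were high. There the median deviations of the calcium, fatty acid and oxidative phosphorylation lists were -0.27, -0.28 and -0.13, against -0.03, -0.04 and -0.03 in replicate 2. Of 19 calcium handling and ion channel genes, Kcnv2 fell over all genes, 5 fell and 1 rose adjusted over the list alone, and the median was -0.28 (camera adjusted p = 0.00889, and 0.721 with an estimated correlation). The potassium channel genes Kcnj3 and Kcnj11 differed by -0.86 and -0.80 and phospholamban (Pln) by -0.62. Of 34 oxidative phosphorylation and citrate cycle genes, 27 were below 0 with a median of -0.13, and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.0145, and 0.721 with an estimated correlation). The Krebs cycle genes Ogdh and Sucla2 differed by -0.58 and -0.78. Of 28 fatty acid oxidation genes, 0 passed over all genes, 3 fell and 1 rose adjusted over the list alone, and the median was -0.27 (adjusted p = 0.0467, and 0.721 with an estimated correlation). The fatty acid transporter gene Cd36 differed by -1.14, Acads by -0.90 and Acot1 by -1.23, while Angptl4, an inhibitor of lipoprotein lipase, differed by 1.77 (adjusted p = 0.0513, 0.0649, 0.0971 and 0.0608). The other 18 lists were not called, with adjusted p from 0.0569 for fibroblast markers to 0.947 for glycolysis. In these the transcription factor gene Tbx20 (1.34 ± 0.20) and the sterol transporter gene Stard4 (not detected in sham, at least 2.07-fold higher) rose.

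At an unadjusted p under 0.05 there were 2364 genes, against 527 by chance, and the groups did not overlap for 53.8% of genes, against 33.3% by chance. In each comparison, genes that move together between arrays can exceed both chance values without an effect of the group. The count of 43 was 0 without any of sham replicate 1, sham replicate 2, TAC_DMSO replicate 1 or either TAC_BIX array. It was 166 without TAC_DMSO replicate 2, with 28 genes in common, and it ran from 0 to 426 across the other settings. The medians of the cell cycle, endothelial and interferon lists were 0.20, 0.25 and 0.56 with the authors' processed values. That of oxidative phosphorylation was -0.29 with median scaling, or -0.205 relative to the median of all genes. Without TAC_DMSO replicate 1 the lists lost were calcium handling and ion channels (adjusted p = 0.164), cell cycle (0.164), oxidative phosphorylation and citrate cycle (0.164) and fatty acid oxidation (0.612). Without sham replicate 1 they were cell cycle (0.339), oxidative phosphorylation and citrate cycle (0.172) and fatty acid oxidation (0.0828), and without sham replicate 2, fatty acid oxidation (0.0748). Over 13 alternatives the estimated correlation gave the highest adjusted p of each of the 8 lists, and the lowest ran from 1.74e-18 for extracellular matrix and fibrosis to 0.00250 for fatty acid oxidation.

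**Figure D2:**
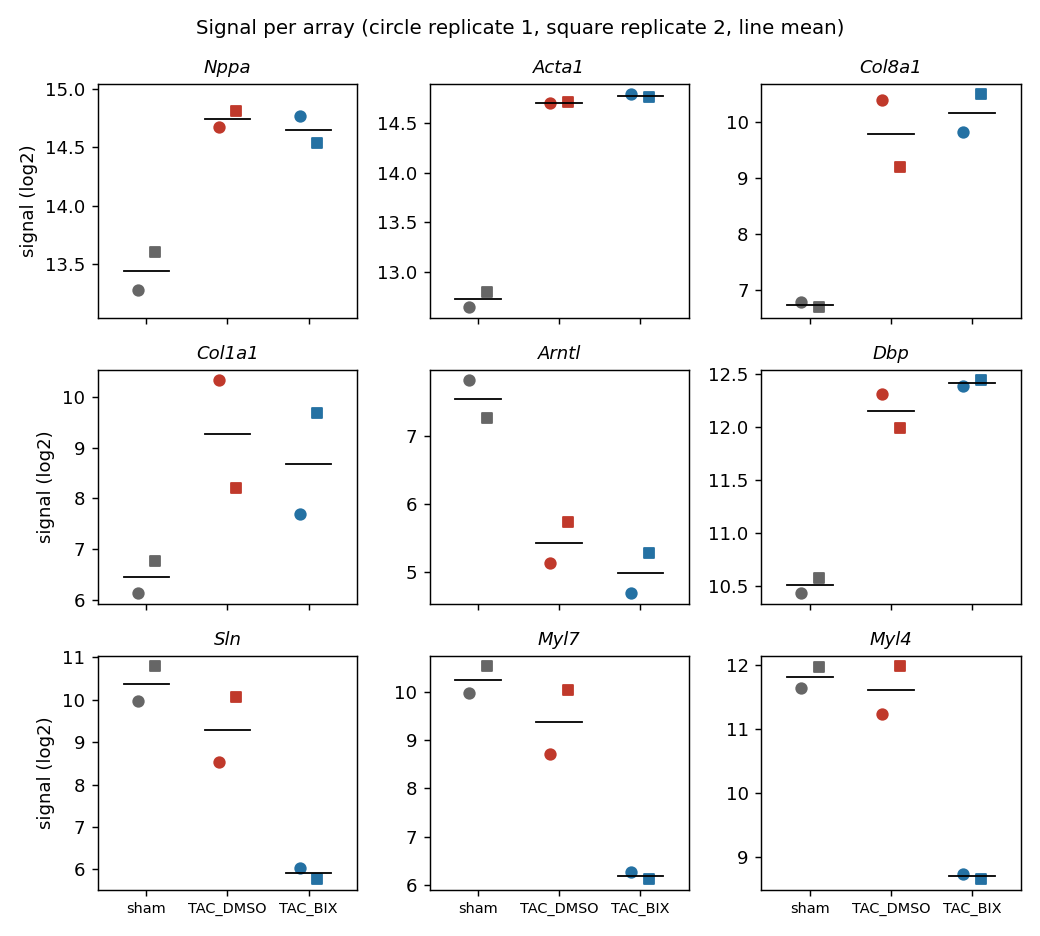
Log2 signal (y axis) of 9 genes in the 3 groups (x axis); circles are replicate 1, squares replicate 2, and lines the mean of 2 arrays. Acta1 and Nppa are higher than sham on all 4 constriction arrays, Col1a1 spreads widely within both constriction groups (SD 1.51 and 1.40), and the atrial genes Sln, Myl7 and Myl4 are lowest on both TAC_BIX arrays.

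The comparison of TAC_BIX with TAC_DMSO asks what the drug changed after constriction, and 0 of 10538 genes were called with limma. The smallest adjusted p was that of Myl4, the atrial essential myosin light chain gene, at -2.93 ± 0.26 log2 (SE), from 11.62 ± 0.52 to 8.69 ± 0.06 (SD, n = 2 per group; adjusted p = 0.0590). Txn1, the thioredoxin gene (-1.59 ± 0.18), the histone gene H4c18 (-1.44 ± 0.17), the lectin gene Clec2d (-1.76 ± 0.22) and the apoptosis-related gene Pdcd5 (-1.29 ± 0.16) followed, each with adjusted p = 0.0652. Of the hypertrophy markers called higher in TAC_DMSO than in sham, Nppa differed by -0.09 ± 0.19 and Acta1 by 0.07 ± 0.17 (adjusted p = 0.828 and 0.848). Both lay near the highest signal measured (14.98) in both groups, so these values do not exclude a difference. Nppb differed by -0.06 ± 0.20, Myh7 by 1.06 ± 0.93, Col1a1 by -0.58 ± 0.78, Col3a1 by -0.05 ± 0.53 with probes that disagreed, and Ccn2 by 0.49 ± 0.37. Of the drug's target genes, Ehmt1 lay at the detection floor and was detected on 1 of the 2 TAC_BIX arrays (-0.11 ± 0.16), and Ehmt2 differed by 0.24 ± 0.17 with probes that disagreed. Myh6 differed by 0.08 ± 0.17, with a further probe at 0.52, and Atp2a2 by -0.03 ± 0.17 with probes that disagreed. Myh6 and Atp2a2 also lay near the highest signal measured, so these values do not exclude a difference.

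Of the lists, 4 were called. Interferon response genes were lower with the drug: 18 of 20 were below 0, with a median of -0.43, 0 passed over all genes, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000870, and adjusted p = 0.684 with an estimated correlation). The antiviral gene Bst2 differed by -1.60, Isg15 by -1.61, the immunoproteasome gene Psmb9 by -1.16 and Cxcl9 by -0.96 (adjusted p = 0.0652, 0.0725, 0.0689 and 0.122). Macrophage and leukocyte markers were lower, with 18 of 21 below 0 and a median of -0.34, and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.0245, and 0.684 with an estimated correlation). Cd52 differed by -1.88, Aif1 by -1.79, H2-Aa by -1.44 and Tyrobp by -1.43. That list stood at a median deviation of 0.70 in TAC_DMSO replicate 1 and -0.22 in replicate 2, against -0.25 and 0.03 in the TAC_BIX arrays. Glycolysis and glucose uptake genes were higher, with 16 of 18 above 0 and a median of 0.40, and 0 passed over all genes or adjusted over the list alone (adjusted p = 0.00732, and 0.684 with an estimated correlation). The glycolytic regulator gene Pfkfb2 differed by 0.98, Ldha by 0.54, Aldoa by 0.49 and Pdk1 by 0.51. Of 7 atrial markers, 0 fell over all genes and 3 fell adjusted over the list alone: Myl4, Myl7 (-3.17 ± 0.40) and Sln, the sarcolipin gene (-3.39 ± 0.48). The list's median was only -0.17 against a mean of -1.29, and Pam differed by 0.65 (adjusted p = 0.0349, and 0.684 with an estimated correlation).

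The other 22 lists were not called, with adjusted p from 0.0745 for autophagy and lysosome genes to 0.616 for endothelial markers. Among their members, Angptl4 differed by -1.90, the neutrophil genes S100a8 by -1.93 and S100a9 by -1.02, and Hspb7, a cardiac small heat shock protein gene, by 0.81 (adjusted p = 0.0652, 0.0652, 0.0882 and 0.0712). The erythroid list had a median of -1.15, the lowest of the lists (adjusted p = 0.185), and TAC_DMSO replicate 2 had the highest erythroid deviation, 1.76, of the 6 arrays.

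Beside the 0 genes called, 2090 genes had an unadjusted p under 0.05 (963 higher and 1127 lower, against 527 by chance), 540 had an adjusted p under 0.1, and the groups did not overlap for 51.7% of genes, against 33.3% by chance. Other settings called 0 to 712 genes, with 712 from log2 quantile normalization without background correction, 642 from the authors' processed values and 699 with an intensity trend and robust prior. The calls were mostly lower: 253 higher and 459 lower with log2 quantile normalization, 127 and 436 with an offset of 50, and 18 and 362 with median scaling. The median of the glycolysis list was 0.11 with median scaling, or 0.145 relative to the median of all genes. Those of the interferon and atrial lists were -0.24 and -0.11 with the authors' processed values. Without TAC_BIX replicate 1 the lists atrial markers (adjusted p = 0.195), interferon response (0.186) and macrophage and leukocyte markers (0.259) were not called, nor was the last without TAC_DMSO replicate 1 (0.727), and atrial markers were not called on ranks (0.143), with the authors' processed values (0.0926) or with log2 quantile normalization (0.0592). Over 13 alternatives the adjusted p ran from 0.000305 to 0.684 for atrial markers, from 7.11e-08 to 0.684 for interferon response, from 1.81e-05 to 0.727 for macrophage and leukocyte markers and from 0.000180 to 0.684 for glycolysis.

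**Figure D3:**
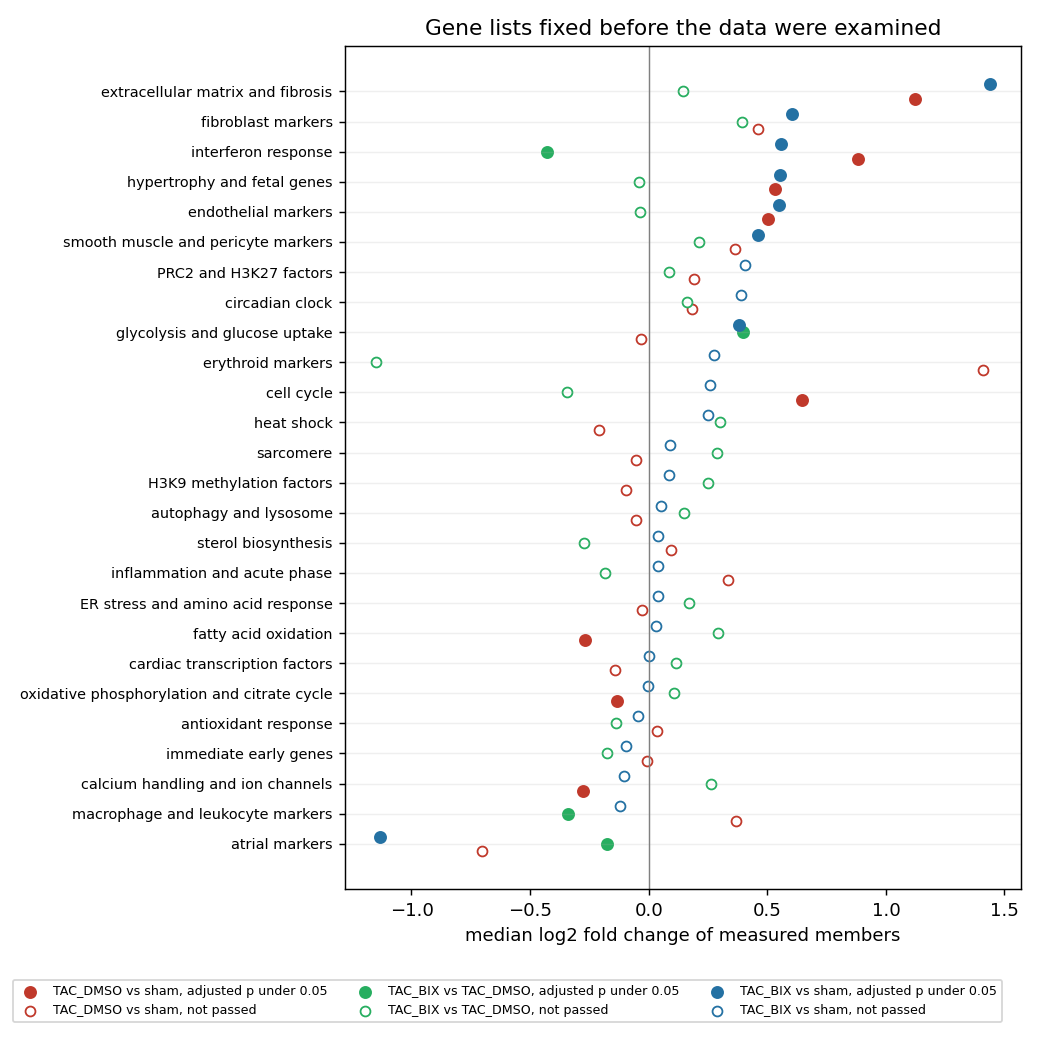
Median log2 fold change of the measured members (x axis) of the 26 tested gene lists (y axis) in the 3 comparisons, shown by colour; filled points had a camera adjusted p under 0.05 at the preset correlation and open points did not. Among the filled points the extracellular matrix list is highest against sham in TAC_DMSO (1.12) and TAC_BIX (1.44), the atrial list is lowest in TAC_BIX against sham (-1.13), and the erythroid list lies higher in TAC_DMSO (1.41) without passing.

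The comparison of TAC_BIX with sham asks which differences from the sham heart were present under the drug. The largest falls were those of Sln, which encodes a regulator of the calcium pump (-4.48 ± 0.48 log2), Myl7, the atrial regulatory myosin light chain gene (-4.04 ± 0.40), Mybphl (-3.18 ± 0.38) and Myl4 (-3.12 ± 0.26; SE, n = 2 per group; limma adjusted p = 0.0136, 0.0136, 0.0161 and 0.0136). The largest rises were those of Col8a1 (10.7-fold), Rgs5, a pericyte marker (9.77-fold), Comp, a cartilage matrix gene (9.33-fold), and Ccn5, a matricellular gene (5.62-fold, adjusted p = 0.0158, 0.0195, 0.0450 and 0.0223). Comp had an SD of 1.95 between the TAC_BIX arrays and a further probe at 0.91 log2, and its call held under 9 of 20 alternatives. Nppa and Acta1 rose 2.31-fold and 4.15-fold (adjusted p = 0.0223 and 0.0136), to 14.65 ± 0.16 and 14.78 ± 0.02, again near the highest signal measured, where a fold can be compressed. Arntl fell by 2.56 ± 0.30, to detection on 1 of the 2 TAC_BIX arrays, and Dbp and Ciart rose by 1.91 ± 0.18 and 1.97 ± 0.18 (adjusted p = 0.0161, 0.0136 and 0.0136).

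Of 701 genes called, 289 were higher and 412 lower, with differences of at least 0.69 log2 in size. Further large rises were the homeobox gene Meox1 (5.51-fold), the elastic fibre gene Mfap5 (5.45-fold), Gask1b (5.11-fold) and the integrin-like gene Itgbl1 (5.08-fold). Svep1 and Cav2 were not detected in sham (4.62 ± 0.08 and 4.52 ± 0.19) and were at least 4.15-fold and 3.41-fold higher. Further large falls were Ano10 (7.79-fold), the tubulin ligase-like gene Ttll1 (4.37-fold) and the acyl-CoA thioesterase gene Acot1 (4.26-fold). Retnla fell from 7.69 ± 0.69 to 4.80 ± 0.34, at the detection floor, and was detected on 1 of the 2 TAC_BIX arrays. Hamp, the hepcidin gene, was not detected in TAC_BIX (4.46 ± 0.08 against 6.65 ± 0.45) and was at least 3.56-fold lower. In the panel, Nppb (0.55 ± 0.20), Myh7 (2.45 ± 0.93), Col1a1 (2.25 ± 0.78), Col3a1 (1.84 ± 0.53) and Ccn2 (0.98 ± 0.37) did not pass (adjusted p = 0.140, 0.149, 0.123, 0.0819 and 0.144). Myh6 (-0.01 ± 0.17, with a further probe at 0.35), Atp2a2 (0.06 ± 0.17) and Ehmt2 (0.27 ± 0.17) did not pass either, nor did Ehmt1, which was detected on 0 sham arrays and 1 TAC_BIX array. Myh6 and Atp2a2 again lay near the highest signal measured.

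All 27 extracellular matrix and fibrosis genes were above sham with a median of 1.44; 5 rose over all genes and 18 rose adjusted over the list alone (camera adjusted p = 6.93e-10, and adjusted p = 0.647 with an estimated correlation). Besides Col8a1, Sparc (2.04), Col6a1 (1.80) and Tgfb2 (1.27) were among these. Of 18 fibroblast markers, 4 rose (Mfap5, Islr at 2.04 and detected on 1 of the 2 sham arrays, the proteoglycan gene Lum at 1.93 and Fbln2 at 1.78) and 8 rose adjusted over the list alone, with a median of 0.60 (adjusted p = 0.00129, and 0.647 with an estimated correlation). Of 13 smooth muscle and pericyte markers, 3 rose (Rgs5, Mylk at 0.96 and Notch3 at 0.87), and 6 rose and 1 fell adjusted over the list alone, with a median of 0.46 (adjusted p = 0.00616, and 0.647 with an estimated correlation). Of 19 endothelial markers, 2 rose (Flt1 at 1.18 and Pecam1 at 1.24, the latter with probes that disagreed) and 6 rose adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00532, and 0.647 with an estimated correlation). These cell type markers differed between the TAC_BIX arrays: the fibroblast list stood at 0.15 in replicate 1 and 0.67 in replicate 2, and the endothelial list at -0.05 and 0.28.

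Of 22 hypertrophy and fetal genes, 5 rose and Myl4 fell, and 12 rose and 3 fell adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00363, and 0.647 with an estimated correlation). Besides Acta1 and Nppa, the actin-binding gene Xirp2 rose by 1.60 and the phosphofructokinase gene Pfkp by 1.52. Of 20 interferon response genes, 3 rose (Ifit2 at 1.21, Usp18 at 1.11, and the RNA sensor gene Ddx58, not detected in sham and at least 1.97-fold higher) and 7 rose adjusted over the list alone, with a median of 0.56 (adjusted p = 0.00310, and 0.647 with an estimated correlation). Of 18 glycolysis genes, 15 were above 0 with a median of 0.38, and 0 passed over all genes or adjusted over the list alone, against 701 of all genes (adjusted p = 0.00616, and 0.647 with an estimated correlation). Ldha differed by 0.65 and Hk1 by 0.87. Of 7 atrial markers, 4 fell over all genes and adjusted over the list alone: Sln, Myl7, Myl4 and Stard10 (-1.13), with a median of -1.13 (adjusted p = 0.00363, and 0.647 with an estimated correlation).

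The other 18 lists were not called, with adjusted p from 0.0502 for the circadian clock to 0.859 for inflammation. Of 14 clock genes 4 rose and 1 fell: besides Ciart, Dbp and Arntl, Per3, not detected in sham, was at least 2.55-fold higher. In the list of endoplasmic reticulum stress and amino acid response, 5 of 27 rose, among them the asparagine synthetase gene Asns (2.06 ± 0.35), the mitochondrial folate enzyme gene Mthfd2 (1.38 ± 0.19), the calreticulin gene Calr (1.26 ± 0.25) and Trib3 (1.20 ± 0.24). Of these, Asns and Trib3 were detected on 1 of the 2 sham arrays. The list's adjusted p was 0.248, and its median of 0.04 changed sign with median scaling. In the immediate early list 4 of 24 fell: Klf4 (-0.96), Nr4a1, at least 1.28-fold lower, Zfp36 (-0.83) and Klf2 (-0.81). In the calcium list Hrc (-1.21), Kcnv2 (-1.51) and Kcnj11 (-1.03) fell and Kcna5, not detected in sham, was at least 1.46-fold higher. Of 34 oxidative phosphorylation genes, 3 fell: Ndufb10 (-1.07), Cox7a1 (-1.04) and Sdha, at least 1.59-fold lower. In fatty acid oxidation Acot1 and Pdk4 (-1.46) fell and Acot2 (1.16, with probes that disagreed) rose; its median of 0.03, mean of -0.11 and camera direction, lower, differed in sign.

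Chromatin lists were not called in any comparison. Of 19 factors of H3K9 methylation, 1 rose in TAC_BIX against sham, the heterochromatin protein gene Cbx3 (1.83 ± 0.27, adjusted p = 0.0218, with probes that disagreed), and in TAC_BIX against TAC_DMSO the list had a median of 0.25 (adjusted p = 0.168). Of 16 PRC2 and H3K27 factors, Bmi1 (0.93 ± 0.19) and Rbbp4 (1.05 ± 0.23, with probes that disagreed) rose in TAC_BIX against sham, as did Ezh1, not detected in sham and at least 1.26-fold higher (list adjusted p = 0.0753). The call of Ezh1 held under 3 of 19 alternatives. Tbx20 rose by 1.68 ± 0.20 with probes that disagreed, Pdlim5 of the sarcomere list rose by 1.27 ± 0.20 and the cardiac troponin I gene Tnni3 fell by 0.80 ± 0.17.

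At an unadjusted p under 0.05 there were 2781 genes against 527 by chance, and the groups did not overlap for 58.4% of genes, against 33.3% by chance. The count of 701 was 2 without sham replicate 1 (Ano10 and Rgs5), 0 without sham replicate 2 or TAC_BIX replicate 2, 216 without TAC_BIX replicate 1, and 0 to 1754 across the other settings. With median scaling the medians of the hypertrophy and glycolysis lists were 0.17 and 0.10. Relative to the median of all genes they were 0.30 and 0.24, against 0.56 and 0.39 in the reported fit. With the authors' processed values the medians of the matrix, interferon and smooth muscle lists were 0.69, 0.22 and 0.17. Of the lists, atrial markers were not called without TAC_BIX replicate 1 (adjusted p = 0.0564) or on ranks (0.0799), endothelial markers without TAC_BIX replicate 2 (0.0704) and glycolysis and glucose uptake without sham replicate 2 (0.0943), within ranges over 13 alternatives of 0.000705 to 0.647, 0.000835 to 0.647 and 0.000304 to 0.647.

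Families of short, abundant transcripts were examined after their values in TAC_BIX against sham were seen, so their counts describe these arrays and are not independent evidence. Of 70 respiratory chain subunit genes 25 fell (35.7%, against 3.70% of other genes), of 56 cytosolic ribosomal protein genes 16 fell (28.6%, against 3.78%), of 18 core histone genes 6 fell (33.3%, against 3.86%) and of 73 mitochondrial ribosomal protein genes 9 fell (12.3%, against 3.85%). With camera, adjusted over 5 sets, the adjusted p at the preset correlation was 8.91e-14, 2.03e-12, 0.000374 and 6.6e-05 in that order. At an estimated inter-gene correlation, a setting with little power here, none was called (adjusted p = 0.245, 0.297, 0.245 and 0.399). In TAC_BIX against TAC_DMSO the families' medians were -0.45, -0.66, -0.40 and -0.41 log2, with 0 members called. There camera gave adjusted p = 1.26e-11, 1.24e-16, 2.84e-07 and 1.36e-09 at the preset correlation, and 0.226, 0.226, 0.0939 and 0.235 with an estimated one. These directions held under every scaling tried. The median was -0.78 for the respiratory chain with median scaling (-0.74 relative to all genes) and -0.22 for histones with the authors' processed values. Of genes in the shortest decile of genomic span 12.0% fell, against 3.02% of other genes (camera adjusted p = 1.04e-06 at the preset correlation and 0.245 with an estimated one). The median deviation of that decile was 0.07 and 0.04 in the sham arrays, 0.17 and 0.09 in TAC_DMSO, and -0.14 and -0.22 in TAC_BIX. Its median in TAC_BIX against TAC_DMSO was -0.28, and -0.10 with the authors' processed values. Probes for ribosomal, histone and hemoglobin genes can also bind transcripts of close paralogs.

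**Figure D4:**
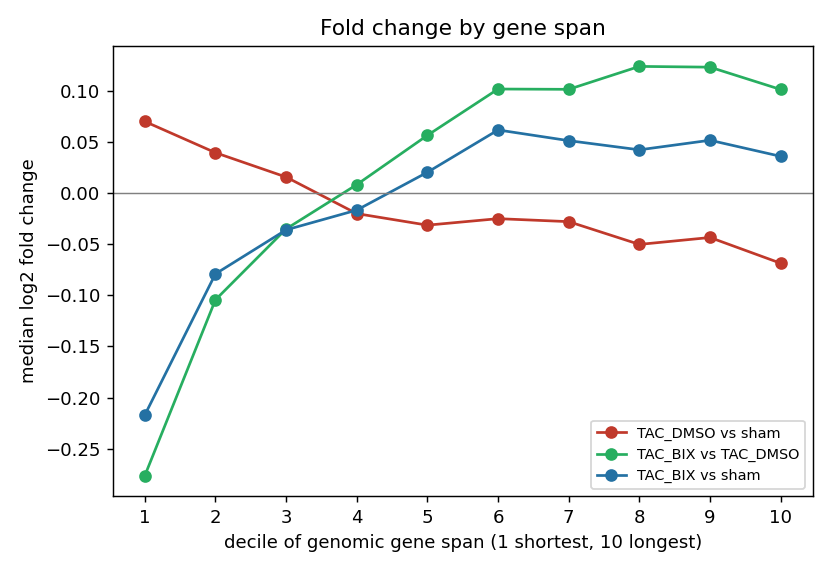
Median log2 fold change (y axis) of the genes in each decile of genomic span (x axis, from shortest to longest), with a line for each of the 3 comparisons. In TAC_BIX against TAC_DMSO the shortest decile is at -0.28 and the longest at 0.10, and in TAC_DMSO against sham they are at 0.07 and -0.07.

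Whether the genes called in TAC_DMSO against sham lay nearer to sham under the drug was described by sign. Of the 43 genes called in TAC_DMSO against sham, 31 lay closer to or past sham in TAC_BIX (72.1%, exact 95% interval 56.3% to 84.7%), and 0 were called in the opposite direction. The interval treats the 43 genes as independent, which genes measured on the same arrays are not. It does not measure the spread between arrays. In TAC_BIX against TAC_DMSO limma called 0 genes in all, and 2090 had an unadjusted p under 0.05. Both differences contain the TAC_DMSO arrays, so opposite signs arise by chance. Simulated groups with the measured differences of TAC_DMSO from sham and no drug effect gave 69.6%, and unchanged groups gave 92.1%. With a different vehicle array in each difference, 43 genes were taken anew by smallest p, and only 11 or 23 of them were among those called. The share of these genes was 34.9% or 69.8%, so it also reflects the change of genes. Those differences share no array, so the simulated shares are no yardstick for these values. The greater part of the difference from sham was undone in 5 of the 43 genes, Afdn, Dctn1, Eif4ebp1, Lsm12 and Slc25a46, singled out after their values were seen. Dctn1 differed by -1.18 and Afdn by -1.27 between drug and vehicle (adjusted p = 0.0652 each).

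Genes called after constriction were compared with those called under the drug. Of the 22 genes higher in TAC_DMSO than in sham, 16 were also called higher in TAC_BIX, and of the 21 lower, 19 were also called lower; 0 of the 35 were opposite. Both comparisons contain the sham arrays, and simulated unchanged groups that shared them had 10.9 (4 to 20 over 100 simulations) and 11.3 (4 to 19) genes in common, with as many genes taken by smallest p. Independent lists of these sizes would share 0.603 and 0.821, a value that leaves out the shared arrays, so part or all of the overlap can come from them. Across genes, which are not independent replicates, log2 differences from sham correlated between TAC_BIX and TAC_DMSO with r = 0.640 and a covariance of 0.150. Simulated unchanged groups that shared the sham arrays gave r = 0.50 and a covariance of 0.0274 (0.0252 to 0.0294 over 100 simulations). With a different sham array in each difference r was 0.416 or 0.422. Those differences share no array, so the simulated r of 0.50 is no yardstick for these values.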

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

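Of the tests below, the gap between the vehicle arrays in atrial genes and the direction of 3 clock genes were chosen after the result was seen; the others were written beforehand.

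Probes with no gene in the platform's annotation took no part in the gene comparisons, and some of them differed from sham. Of 2827 such kept probes, 30 were higher and 38 lower in TAC_DMSO than in sham, and 105 were higher and 245 lower in TAC_BIX than in sham, when all 19273 kept probes were tested with limma. In TAC_BIX against TAC_DMSO 0 of them were called, and every kept probe together gave 1 call.

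A set of atrial transcripts fell together against sham in the TAC_BIX arrays, where Sln measured 6.03 and 5.77 log2, against 8.52 and 10.07 in TAC_DMSO and 9.97 and 10.79 in sham, and Myl7, Myl4 and Mybphl were also lowest on both TAC_BIX arrays. If the TAC_BIX preparations held less atrial tissue, 6 further atrial-enriched genes (Angpt1, Fgf12, Gja5, Kcnj3, Kcnj5 and Tbx5) would be lower as well. Their median difference from TAC_DMSO was 0.192, with 0 of 6 below 0, while from sham it was -0.281, with 5 of 6 below 0. The first median had an SE of 0.117 from resampling the 6 genes, which does not measure the spread between arrays. The median of 0.192 passed the limit set beforehand against this explanation, yet the limit was not a fair one. These genes lay a median of only 0.50 log2 above the detection floor, too little room for a fall of the size seen. The fall held in all 4 pairs of TAC_BIX and TAC_DMSO arrays (medians of -3.74 to -2.46), but the vehicle arrays themselves differed by a median of 1.30 in these genes, so the content of atrial genes varied without the drug. Less atrial tissue and a lower expression of atrial genes after BIX-01294 cannot be told apart here, since the second set of genes was too weakly expressed and the 2 arrays per group give no measure of dissection.

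The clock genes Arntl, Dbp and Ciart stood apart between sham and both constriction groups. If hearts were collected at another time of day, further rhythmic genes would follow their phase: of those that peak with Dbp, Lonrf3, Tspan4 and Tsc22d3 were measured and had a median difference from sham of -0.195 in TAC_DMSO (-0.19, 1.06 and -0.24) and of 0.0534 in TAC_BIX (-0.84, 0.76 and 0.05). No gene of the opposite phase was measured, so the contrast of phases that was planned could not be formed. A change of the clock by constriction itself predicts the same direction in both constriction groups, which held for 3 of 3 genes, but a shared collection time predicts that too. The times of collection are not given in the sources used here, and the explanations cannot be told apart.

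Short genes were lower in the TAC_BIX arrays than in TAC_DMSO, among them ribosomal, respiratory chain and histone genes. A loss of short RNA, or a difference in RNA quality, predicts that short genes of other kinds fall as well; the 919 genes of the shortest decile outside these families had a median of -0.236, with -0.291 to -0.178 in the 4 array pairs. These are most of the 1053 genes that make up the pattern, so the value restates it and does not test the explanation. A lower expression of ribosomal protein and respiratory chain genes as classes predicts that their long members fall too; 15 members with a span above the median of all genes had a median of -0.0855, with -0.211 to 0.0675 in the 4 pairs, against -0.541 for 184 short members. These 15 genes are too few to decide, and with genomic span in place of transcript length and no measure of RNA integrity per array, the explanations cannot be told apart.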

How the results depend on the processing

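The number of genes called depended on the processing. Of the named genes' values under the alternatives, 0 reversed as calls, but many alternatives could not have reversed one. Other thresholds, another prior and the replicate term leave a difference as it is. Called genes had groups that did not overlap, so leaving out an array keeps their sign. Of the values, 2034 of 2657 in TAC_BIX against sham, 2357 of 2506 in TAC_BIX against TAC_DMSO and 2279 of 2676 in TAC_DMSO against sham kept their side of the threshold. Of the rest, 536, 0 and 259 lost a call and 87, 149 and 138 gained one in that order, and 21, 21 and 14 values that were not called had the other sign. In TAC_BIX against sham the calls of Ezh1, Insig1, Txnrd1 and Usp18 held under only 3, 6, 6 and 7 alternatives, against 16 of 20 for Acta1. In TAC_DMSO against sham those of Stard4, Cav2 and Nppa held under 4, 5 and 7, against 12 of 20 for Acta1. With 2 arrays per group the calls rest on a spread shared over the 3 groups, and where an array was left out the lone array was assumed to vary like the others. Genes near the detection floor or the top of the scale show compressed differences. A slide as a block was not run, since no slide is given. The span trend removal was chosen after seeing the data. For the differences below the cause was not tested.

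Genes called in TAC_DMSO against sham (43), TAC_BIX against TAC_DMSO (0) and TAC_BIX against sham (701) became, in that order, 227, 712 and 940 with log2 quantile normalization without background correction, 151, 380 and 1294 with median scaling, 275, 563 and 997 with an offset of 50, and 93, 642 and 820 with the authors' processed values. They were 1 (Acta1), 0 and 369 without the detection filter, 134, 359 and 839 with detection on all 6 arrays, and 294, 1 (a probe of Myl4) and 1754 with every kept probe on its own. With an intensity trend and robust prior they were 426, 699 and 1136, and at an adjusted p under 0.01 they were 0, 0 and 0. Array weights gave 15 in TAC_DMSO against sham, its 4 arrays alone 0, and the span trend removed 17. With a replicate block, a term for the replicate number, they were 0, 0 and 253, although deviations from the group mean did not pair by number (r = 0.09, -0.24 and -0.16 across genes between groups), and fatty acid oxidation lost its call in TAC_DMSO against sham (adjusted p = 0.0553, within 0.00250 to 0.721 over its 13 alternatives). Of the calls in TAC_BIX against sham, 28.7% were higher with median scaling, against 41.2% in the reported fit.

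Leaving out each array in turn gave 0 to 166 genes in TAC_DMSO against sham, 0 to 6 in TAC_BIX against TAC_DMSO and 0 to 738 in TAC_BIX against sham. The 6, named after their values were seen, were Igtp, Mybphl, Myl4, Myl7, Sln and Vmn1r65, all lower without TAC_DMSO replicate 1. Without TAC_DMSO replicate 2 the genes called were AA467197, Clec4d, Myl4, Sprr1a, Timp1 and Tnc, again all lower. Lists called ran from 5 to 12, 5 to 10 and 7 to 14 in these 3 comparisons, against 8, 4 and 8. With an estimated correlation the lists called were 0, 0 and 0, but this setting has little power with 2 arrays per group. In TAC_DMSO against sham it left a simulated shifted list of independent genes at camera adjusted p = 0.118. There it also gave 0.721 for hypertrophy and fetal genes, whose estimated correlation was only 0.07. In TAC_BIX against TAC_DMSO the lists called were 13 without the detection filter and 8 with the span trend removed. All 20 called lists kept their direction under all 13 alternatives.

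The share of constriction genes moved back (72.1%) ran from 62.8% to 74.4% with an array left out. It was 34.9% with constriction measured from vehicle array 1 alone and the drug from vehicle array 2 alone. That value is for 43 genes taken anew by smallest p, of which 11 were among those called. With the vehicle arrays exchanged the share was 69.8%, with 23 genes in common. The correlation of differences from sham (0.640) was 0.566 with log2 quantile normalization, 0.547 with the authors' processed values and 0.576 to 0.690 with an array left out. It was 0.416 and 0.422 with different sham arrays, where the differences no longer share an array.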

Other observations

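In TAC_BIX against sham 18 of 22 antioxidant and 13 of 15 heat shock genes did not pass, and the few called lay in both directions. Of all 10538 genes, 701 were called. Of 22 antioxidant response genes, the quinone reductase gene Nqo1 (1.04 ± 0.18) and the epoxide hydrolase gene Ephx1 (1.05 ± 0.25) rose, while Txnrd1 (-0.72 ± 0.17) and Sod1 (-0.69 ± 0.16, with probes that disagreed) fell (list adjusted p = 0.714). Of 15 heat shock genes, Hspb7 rose (0.84 ± 0.17) and the mitochondrial chaperonin gene Hspe1 fell (-1.55 ± 0.27; list adjusted p = 0.408). The neutrophil gene S100a8 fell (-1.53 ± 0.26) among 26 inflammation genes (list adjusted p = 0.859), Insig1, a brake on sterol synthesis, rose (1.11 ± 0.26, detected on 1 of the 2 sham arrays) among 16 sterol genes (0.832), the vacuolar ATPase gene Atp6v1h rose (0.82 ± 0.19) among 27 autophagy and lysosome genes (0.303), and Ccnd1 rose (0.77 ± 0.17) among 25 cell cycle genes (0.0753). The median of the inflammation list was 0.04 although camera gave it the direction lower. In TAC_DMSO against sham median, mean and camera direction also differed for the endoplasmic reticulum stress list (-0.03, 0.11, higher; adjusted p = 0.464) and the H3K9 list (-0.10, 0.01, lower; adjusted p = 0.631).

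Other tested lists of cell types and cell functions did not pass in TAC_BIX against sham: macrophage and leukocyte markers (adjusted p = 0.408, 0 of 21 members called with limma, against 701 of all 10538 genes), erythroid markers (0.558), the sarcomere (0.202), oxidative phosphorylation and citrate cycle (0.336), immediate early genes (0.411), calcium handling and ion channels (0.410), fatty acid oxidation (0.714), cardiac transcription factors (0.750) and H3K9 methylation factors (0.437). In TAC_DMSO against sham the erythroid list had a median of 1.41 (adjusted p = 0.0856) with Hbb-bs at 2.76 ± 0.90, and macrophage markers a median of 0.37 (0.103). Smooth muscle and pericyte markers had a median of 0.36 there (0.0660), with Rgs5 at 2.73 ± 0.45 (adjusted p = 0.0544). Of the lists too small to test, the adipocyte genes Cidea and Plin4 differed by 0.55 and -0.48 in TAC_DMSO against sham (adjusted p = 0.138 and 0.150). In the germline list Tuba3a, not detected in sham, rose in TAC_BIX and was at least 1.35-fold higher. The Y-linked genes Eif2s3y, Kdm5d and Uty differed from sham by 0.12, 0.44 and -0.45 in TAC_DMSO and by 0.10, 0.34 and -0.19 in TAC_BIX (adjusted p = 0.808, 0.218, 0.277, 0.837, 0.283 and 0.637).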
